A study of Oryza sativa with 6 samples.

How the data were processed

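RNA from the leaf blade and the leaf sheath of rice seedlings was measured on 6 Agilent 2-colour arrays, 3 for each of 2 tissues. Per the labels, the cultivar was Nipponbare and the plants were 2 weeks old, grown in soil at 28 °C under 16 h of light and 8 h of dark, with a labelled time of 2 h. On every array RDD2-OX RNA, from plants overexpressing the gene RDD2, carried Cy5 and wild-type (WT) RNA carried Cy3. The labels name 3 independent RDD2-OX lines and 400 ng of RNA per labelling. No array had the dyes swapped, so a dye bias of a probe stays in every ratio of RDD2-OX to WT and cancels only where blade and sheath are compared.

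The deposited scanner files came from Agilent Feature Extraction 10.5.1.1. They give, per the file headers, the intensity of each spot and of its local background in both channels, with no normalization. They also hold processed signals, which the authors' software had corrected for background and dye, as intensity. The ratio column of the deposited files is the log10 of Cy5 over Cy3. The deposited series matrix holds the same log10 ratios: its largest difference from that column was 0, and its column medians were 0 on 5 arrays and -0.00263 on sheath array 3. The deposited files further give flags of 0 or 1 per spot, for signal well above background, saturation and outliers (other unit). Each array had 45151 spots, of which 43254 were used after 1897 control spots were left out.

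Background was subtracted with normexp (offset 50), and the log2 ratios were normalized by loess within each array with control spots at weight 0 (limma 3.58.1, R 4.3.3). Spots with a non-uniformity or population outlier mark, 12 to 26 per array, were left out, and spots of a probe were averaged. Genes follow the rice locus in the probe name. Where a gene had several probes, the probe with the highest mean intensity stood for it. Genes well above background in at least 1 channel on all 3 arrays of at least 1 tissue were tested, 25403 in all. Of these, 194 had no rice locus, among them 2 control probes from other plants that the files do not mark as controls; 0 of these 2 were called in any comparison. None of the 29690 rice loci on the array matched the reference table, which uses other identifiers, so positions are given only as the chromosome and order that the locus name carries. Neither the probe descriptions nor the reference table name RDD2. Its own ratio therefore has no value here, and the genes annotated as Dof proteins are given in its place.

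Changes in blade, in sheath, on average over both tissues, and their difference (blade minus sheath) were tested with limma's lmFit and eBayes on the log2 ratios of all 6 arrays. WT and RDD2-OX tissues were compared within a dye on the separate channels after Aquantile normalization. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05; a second count asks for at least 2-fold. All tests are two-sided. They measure only the spread between these arrays.

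The WT channels were compared with each other to find shared RNA. The SD of the log2 difference between WT channels was 0.110 for blade arrays 2 and 3 and 0.0823 to 0.0888 for the 3 sheath arrays, below the median SD of repeat spots within an array, 0.178. For WT blade array 1 against arrays 2 and 3 it was 0.687 and 0.681, and between RDD2-OX channels of a tissue it was 0.251 or more. The WT channels were therefore taken as 2 RNAs in blade and 1 in sheath, against 6 RDD2-OX RNAs. The sheath test thus leaves out the spread between WT plants. A fit with each WT RNA counted once was added after this was seen. The WT tissue comparison was fixed with all 6 channels apart. It was changed to each WT RNA once for the same reason, and the fit as first fixed is given as an alternative. In genotype comparisons, the fit with each WT RNA once takes the channels as separate samples, without their pairing on an array. Lower counts from it may reflect the loss of that pairing as well as the shared WT RNA. Blade array 1 was on slide 1, scanned on another day than the rest, blade array 2 on slide 2, and blade array 3 with the 3 sheath arrays on slide 3. The files do not say which array had which line. Same-numbered replicates of blade and sheath were paired by a rule that asked for a correlation above 0.1 of their deviations from the tissue means: the 3 values were 0.133, 0.315 and 0.108, and other pairs ranged from -0.320 to 0.238. In the RDD2-OX channel alone they were 0.0552, 0.317 and 0.0904, of which 1 is above 0.1, so that the pairing is weak. The fit with the replicate as a block is given as an alternative.

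Before the data were examined, 40 lists of genes were fixed from loci and from words in the array's descriptions, and 39 had at least 3 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the 39 lists. These tests were fixed for blade and for sheath; those of the average, the difference and the tissues were added after the data were seen. Camera compares a list with all other genes; fry asks only whether a list's genes move one way on balance. Camera leaves out members with a missing value, so 299 of 301 ribosomal protein genes and 12 of 13 clock genes entered it. 2 fixed loci, Os07g0261200 and Os02g0306401, had no probe.

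The genes named were set by a rule fixed at the same time. It took the 10 highest and 10 lowest changes in blade and in sheath, and the 5 highest and 5 lowest in the other comparisons. These were called genes with signal well above background and an informative description. In blade, in sheath and on average they had 1 sign on all arrays of the group. For the difference and between tissues, the values of blade and sheath arrays did not overlap. Every called clock, flowering or Dof gene was named too, and up to 4 members with the lowest p of each list described. Last came up to 3 genes per tissue measured in 1 genotype only. For the last, the dim signal was raised to the lowest signal that passed as well above background on its array, where it was below that, which gives a lower bound of the fold change. Any other gene was chosen after its values were seen, which is said where it appears. Descriptions are those of the array.

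The tests were checked on simulated data drawn with each gene's spread on these arrays, with 200 changed genes among 25381. Arrays and genes were drawn as independent. The rates found therefore leave out the shared WT RNAs, the slides and the correlation between genes, and do not show how the tests fare under these. Changes of 4-fold were found for 100% of genes in blade, 94.0% in sheath and 85.1% in the difference, and changes of 2-fold for 79.1%, 76.1% and 34.3%, with 14, 8 and 9 false calls. Other settings for background, scaling, filters, probes, variance, blocks and left-out arrays were run as alternatives. Fixed alongside the lists were all of these but the fits with each WT RNA once and without genes seen or missing in WT sheath alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value.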

Results

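Transcript levels in rice plants overexpressing RDD2 (RDD2-OX) were measured against WT plants in the leaf blade and in the leaf sheath, the lower part of a grass leaf that wraps the stem. Each tissue had 3 arrays, and each array held RDD2-OX and WT RNA in different dyes. The labels give 3 independent RDD2-OX lines. The WT channels, however, carried 2 RNAs in blade and 1 in sheath, as judged from their likeness. The median signal above background was 243 to 291 in WT blade, 516 to 736 in RDD2-OX blade, 654 to 669 in WT sheath and 1068 to 1353 in RDD2-OX sheath. Between 76.3% and 84.0% of spots were well above background, and 0 spots were saturated. Log2 ratios are RDD2-OX over WT throughout, given as mean over 3 arrays unless stated otherwise. The SE of a ratio is limma's, from a spread pooled over the arrays of both tissues and moderated across genes by eBayes. It is therefore not the SE of the 3 arrays of a tissue alone.

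The blade comparison asked which transcripts differ between RDD2-OX and WT leaf blades. Several genes of the cell wall fell in RDD2-OX blades. Of the cellulose synthase genes, which make the main fibre of plant cell walls, Os07g0208500 fell by 1.27 (SE 0.09), Os05g0176100 by 1.26 (SE 0.10) and Os07g0252400 by 1.02 (SE 0.10) on the log2 scale, or by 2.41-fold for the first. A pair of genes for fasciclin domain proteins, a family of cell surface glycoproteins, fell as well: Os03g0788600 fell by 1.59 (SE 0.17) and Os09g0248100 by 1.04 (SE 0.09). The beta-tubulin gene Os03g0661300, for a subunit of microtubules, fell by 1.37 (SE 0.13).

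The largest falls among the named blade genes were in Os07g0645000, an allergen V5/Tpx-1 family gene (log2 ratio -2.02, SE 0.22), and in Os02g0568200, annotated as non-phototropic hypocotyl protein, a family with roles in blue-light bending (-1.74, SE 0.14, or 3.33-fold lower). A second allergen V5/Tpx-1 gene, Os08g0459300, stood at -1.70 (SE 0.09), the receptor-like kinase gene Os03g0223000 at -1.55 (SE 0.16) and the Hsp70 chaperone gene Os06g0212900 at -1.52 (SE 0.14). The NAC transcription factor gene Os07g0683200 fell by 1.43 with an SD of 0.05 over its arrays, and the glycoside hydrolase gene Os09g0494200 fell by 1.30. Genes that rose were the cyclin-like F-box gene Os12g0108500 by 1.39 (SE 0.07, 2.62-fold), the PAPS-reductase-like gene Os07g0509800 by 1.32, the CIPK-like kinase gene Os03g0319400 by 1.20, the EF-hand gene Os07g0619200 by 0.86 (with another of its probes of opposite sign) and the bHLH gene Os03g0391700 by 0.81. Adjusted p-values of these genes ran from 0.00937 to 0.0488, and each had its sign on 3 of 3 blade arrays.

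**Figure D1:**
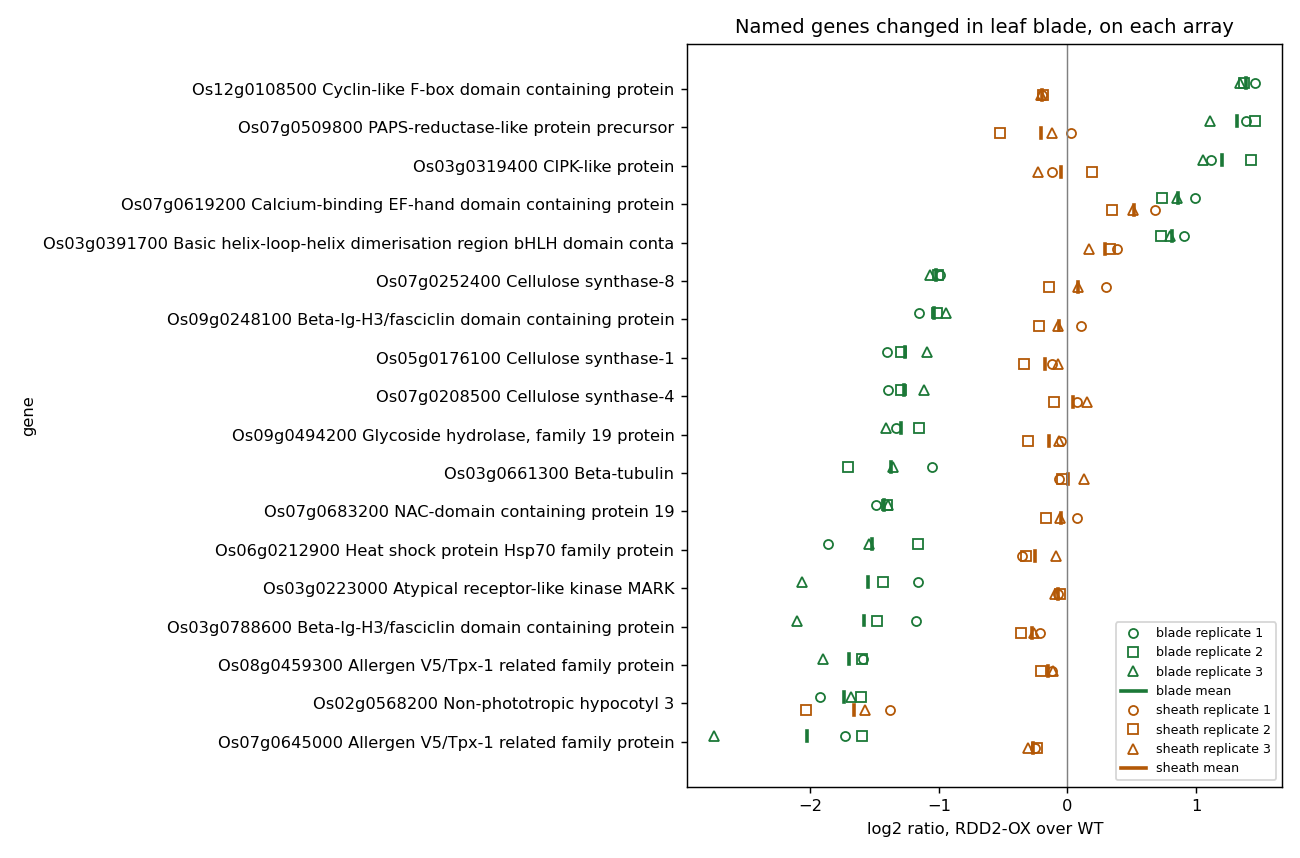
Log2 ratio of RDD2-OX over WT (horizontal axis) of the named blade genes (vertical axis), with a marker for each replicate in blade (green) and sheath (orange) and a line at each mean. Blade values of Os07g0208500 lie around its mean of -1.27 while its sheath mean is 0.04.

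In all, 39 of 25403 genes were called changed in blade by limma, 6 higher and 33 lower, and 26 of them by at least 2-fold. The split by direction depends on the scaling: it was 68 higher and 76 lower from the processed signals, 63 and 73 from the series matrix, and 4830 and 3804 with median centring. In the test as reported 4090 had an unadjusted p under 0.05. With each WT RNA counted once, limma called 0 blade genes (747 at an unadjusted p), and with the replicate as a block also 0 (4375 at an unadjusted p). Without blade array 1 there were 760, and without blade array 3 there were 0 (3801 at an unadjusted p). Blade arrays 2 and 3 share 1 WT RNA, so the 760 leave out the spread between WT plants. Of the 39 genes, 39 remained without blade array 1, 10 without blade array 2 and 0 without blade array 3.

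Of 68 secondary wall and lignin genes, 2 fell, the fasciclin genes named above, and 66 did not pass the test. The list had a median of -0.34 (camera adjusted p = 7.65e-10, or 0.476 with an estimated correlation). Adjusted over the list alone, 20 fell and 2 rose. The phenylalanine ammonia-lyase gene Os02g0626100, for the entry enzyme to lignin, had a log2 ratio of -1.55 with adjusted p = 0.0755. Of 43 xyloglucan and cellulose genes, 3 fell, the cellulose synthase genes named above, and 40 did not pass (median -0.11, camera adjusted p = 0.000305; adjusted p = 0.476 with an estimated correlation); 7 fell adjusted over the list alone. Of 301 ribosomal protein genes 0 passed in limma's gene test, while the list had a median of 0.19 (camera adjusted p = 6.30e-05; adjusted p = 0.989 with an estimated correlation).

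Of 10 photoreceptor genes 0 passed, and 2 rose adjusted over the list alone; the list's median was 0.17 (camera adjusted p = 0.0334; adjusted p = 0.476 with an estimated correlation). In blade this call was lost with the processed signals (0.114), the series matrix (0.103), the mean over all probes (0.0729), and without blade array 1 (0.123) or blade array 3 (0.142). Phytochrome C, Os03g0752100, a red-light receptor, had a log2 ratio of 0.49 (adjusted p = 0.150), and phytochrome B, Os03g0309200, of 0.35 (adjusted p = 0.177). The 5 HD-ZIP III genes, regulators of leaf polarity and vessels, had a median of -0.10 and a fry adjusted p of 0.00276. Their camera adjusted p was 0.0732, or 0.476 with an estimated correlation, and under median centring the blade median turned to 0.02. Of the 52 genes of the ethylene list 2 fell, and both belong to methionine synthesis rather than to ethylene signalling: the methylenetetrahydrofolate reductase gene Os03g0815200 (-1.17) and the methionine synthase gene Os12g0623900 (-0.97; camera adjusted p of the list 0.435). The photosystem list did not pass in blade (camera adjusted p = 0.178), where its 1 called member, Os12g0454600, is annotated as plastocyanin-like and stood at -1.02. Starch genes had 0 calls (camera adjusted p = 0.613), with 3 higher and 10 lower adjusted over the list alone; starch synthase Os06g0160700 stood at -0.66 with adjusted p = 0.0685.

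The sheath comparison asked the same of the leaf sheath. A gene for a Bowman-Birk proteinase inhibitor, Os01g0127600, a class of defence protein, rose by 7.05 (SE 0.93), with 8.66, 4.59 and 7.90 on the single arrays (SD 2.17). Os01g0147700, with an XS zinc finger, rose by 4.04 (SE 0.23), or 16.5-fold, and Os01g0781000, for VPS28, part of the machinery that sorts membrane proteins for the vacuole, by 3.74 (SE 0.08), or 13.3-fold. Os06g0681200, annotated as plastocyanin-like, fell by 3.19 (SE 0.32), and Os01g0827400, for a PRA1 protein of vesicle traffic, by 2.94 (SE 0.10). A chalcone synthase family gene, Os04g0116800, fell by 2.52 (SE 0.07); it was not well above background in blade.

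Other named sheath genes that rose were Os03g0299200 for a dehydrogenase (2.85), Os04g0326300 with a SAM-binding motif (2.49), Os03g0379500 for ribosomal protein S9 (2.15), Os01g0144100 for a thylakoid lumen protein (2.10), Os06g0254300 for a caleosin, a protein of oil bodies (2.08), Os01g0138900 for a racemase family enzyme (1.85) and Os08g0250700 with a thioredoxin domain (1.70). Those that fell were the kinase gene Os01g0116400 (-2.16), the basic secretory protein genes Os10g0491000 (-2.04) and Os10g0490800 (-1.76), the protease gene Os05g0146700 (-1.73), the non-phototropic hypocotyl gene Os02g0568200 (-1.66), the transferase gene Os08g0112200 (-1.56) and the oxygenase gene Os06g0255100 (-1.44). Adjusted p-values of the named sheath genes ran from 1.28e-05 to 0.0382, each with its sign on 3 of 3 sheath arrays. Another 3 genes were well above background in RDD2-OX sheath and not in WT sheath: Os01g0148400 with a Brix domain was at least 103-fold higher (adjusted p = 7.92e-06), the IN2-2 gene Os04g0338100 at least 61.7-fold (adjusted p = 1.63e-05) and the kinase gene Os02g0615800 at least 27.5-fold (adjusted p = 2.23e-05). In blade the highest such bound among described genes was 2.13-fold, for the bZIP gene Os02g0247100 (adjusted p = 0.0939).

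In all, limma called 284 sheath genes, 188 higher and 96 lower, and 173 of them by at least 2-fold; 3449 had an unadjusted p under 0.05. With each WT RNA counted once 51 were called, 40 higher and 11 lower, and all 51 were among the 284; of the named genes these held Os01g0147700, Os01g0781000, Os04g0326300, Os06g0254300, Os08g0250700, Os01g0827400, Os04g0116800 and Os05g0146700. The sheath test leaves out the spread between WT plants, since its WT channels shared 1 RNA, and the replicate block gave 189 genes. Without sheath array 1 there were 116 and without sheath array 3 there were 93; trend and robust variance gave 46 (44 higher, 2 lower).

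The sheath calls lay close together along the chromosomes. Of the 284 genes, 138 had another called gene within 5 tested loci, where random sets of as many tested genes had 30.3 on average and at most 59 (permutation p = 1e-04, the smallest that 10000 draws can give). From Os01g0144100 to Os01g0148500, 10 of 18 tested loci changed, and from Os11g0214400 to Os11g0215100, 4 of 4. The median blade ratio over these stretches was -0.02 and -0.06. This count was chosen after the sheath calls were seen. Runs of at least 4 called genes, each within 5 tested loci of the next, held many named sheath genes. Among these were Os01g0127600, Os01g0144100, Os01g0147700, Os01g0148400, Os01g0781000, Os02g0615800, Os04g0116800, Os04g0326300, Os06g0254300, Os06g0255100 and Os10g0137700. Os01g0827400, Os05g0146700 and Os08g0250700 lay outside them. Passing with each WT RNA counted once does not settle whether a call comes from RDD2-OX or from the 1 WT RNA of the sheath.

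**Figure D2:**
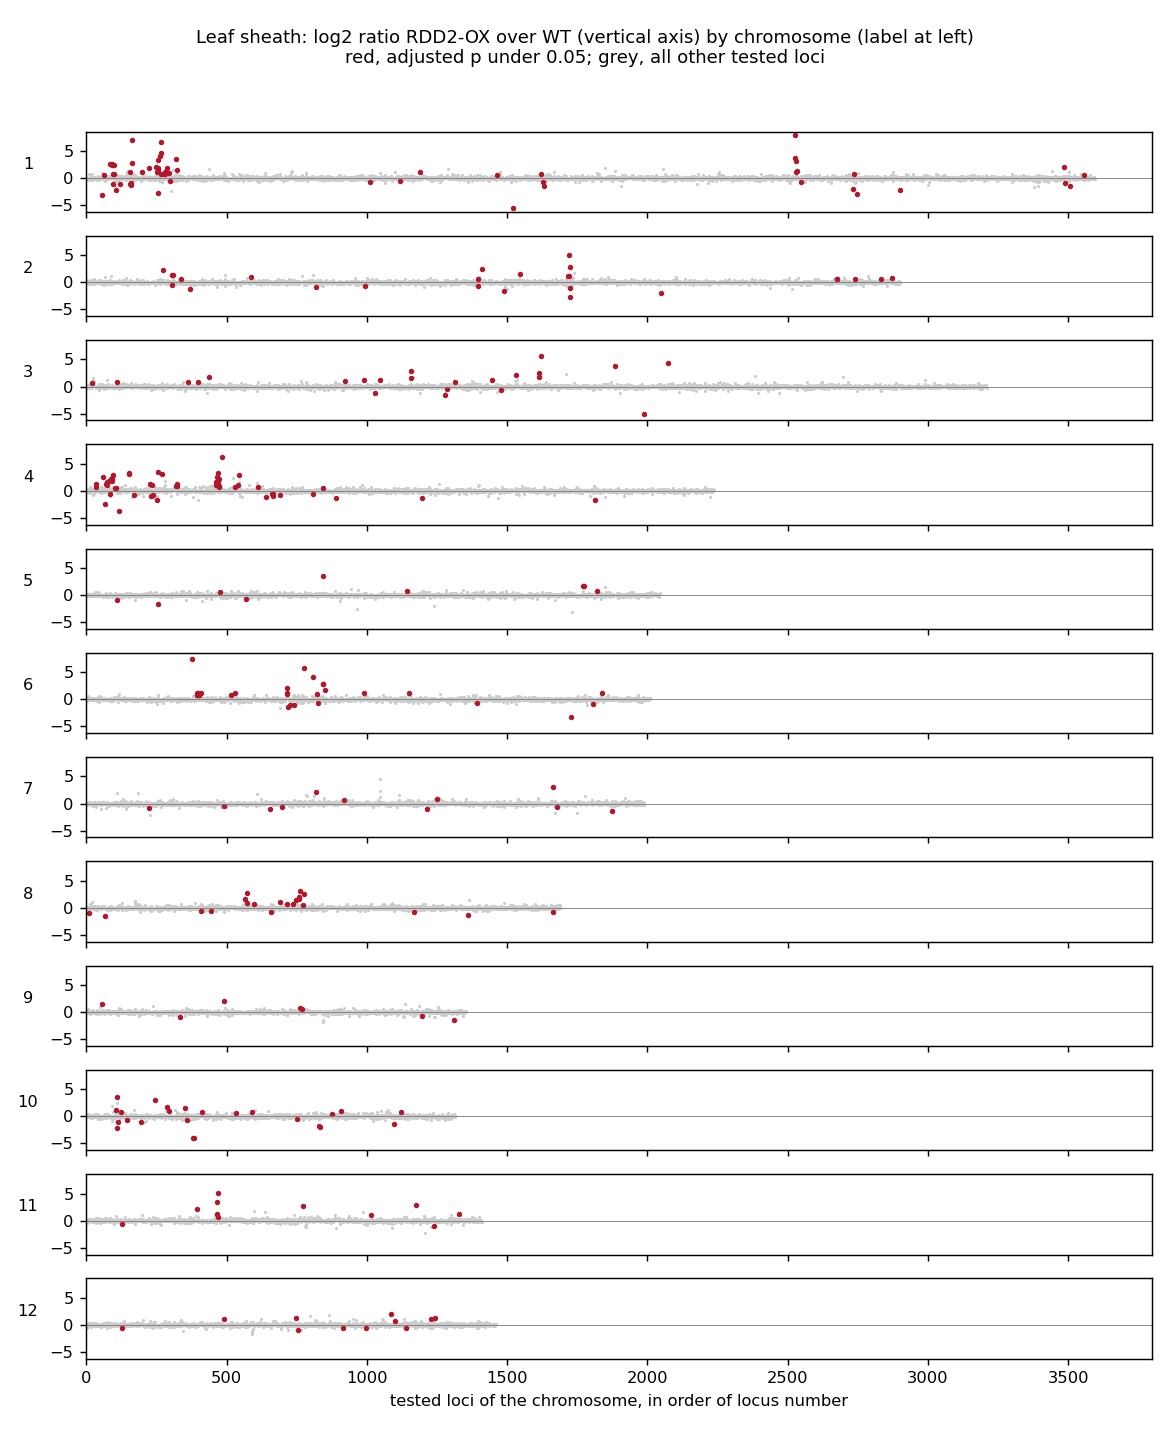
Log2 ratio of RDD2-OX over WT in sheath (vertical axes) of each tested gene by its order along each of the 12 chromosomes (horizontal axes), mean of 3 arrays; red marks the 284 called genes. Called genes stand in groups, such as the 10 of 18 loci near the start of chromosome 1.

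The 17 light-harvesting genes, for the antenna proteins that bind chlorophyll, had a median of 0.48 (camera adjusted p = 0.00340; adjusted p = 0.930 with an estimated correlation), though 0 of them passed limma's gene test, adjusted over all genes or adjusted over the list alone. Os02g0197600 and Os03g0592500, both for chlorophyll a/b-binding proteins, each had a log2 ratio of 0.78, with adjusted p = 0.223 and 0.269. The 66 photosystem genes had a median of 0.22 (camera adjusted p = 0.0358, or 0.930 with an estimated correlation). The 1 member that passed, Os06g0681200, fell, and it entered the list as plastocyanin-like, not as a photosystem protein. Without sheath array 1 neither list passed (adjusted p = 0.112 for light harvesting, 0.367 for photosystems). The photosystem list also lost its call with the processed signals (0.0504), the mean over all probes (0.0562), slide as a random block (0.163) and without blade array 3 (0.0582). Ribosomal protein genes had a median of -0.17 (camera adjusted p = 1.27e-05; adjusted p = 0.957 with an estimated correlation), against the direction of Os03g0379500, the 1 of 301 that passed. Under median centring the ribosomal median in sheath turned to 0.06 (adjusted p = 0.797).

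The 5 shoot meristem markers, KNOX homeobox genes that are active in the growing tip, had a median of -0.91 in sheath (camera adjusted p = 0.0358; adjusted p = 0.930 with an estimated correlation) and 0 passed the gene test. The call in sheath was lost with scaling between arrays (0.0649), the processed signals (0.0504), slide as a random block (0.248) and on leaving out any array but sheath 2 (0.0653 to 0.194), and the list could not be tested under the stricter filter. OSH6, Os01g0302500, read -1.15, 0.09 and -1.04 on the 3 arrays, and OSH15, Os07g0129700, read -1.97, 0.42 and -1.17. Of 134 defence protein genes 2 rose and 3 fell (camera adjusted p = 0.991). Besides the proteinase inhibitor Os01g0127600, the thaumatin gene Os10g0412700 rose by 0.58, while the chitinase genes Os10g0543400 and Os01g0303100 fell by 1.34 and 0.82. The secondary wall list had a median of -0.08 in sheath (camera adjusted p = 0.182), or 0.05 under median centring. The expansin gene Os03g0102500 rose by 0.61 and the cellulose synthase family gene Os07g0551500 fell by 1.07. In the list of histones and cell cycle, which mostly holds F-box proteins of the cyclin-like class, 6 genes rose and 3 fell in sheath (camera adjusted p = 0.793), among them the F-box gene Os10g0137700, which was not well above background in WT sheath.

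The difference between tissues asked whether RDD2-OX moved a gene by another amount in blade than in sheath. Os01g0827400 (PRA1) was higher by 3.28 in blade than in sheath (SE 0.14), Os01g0116400 by 1.99 (SE 0.26), Os05g0146700 by 1.74 (SE 0.10), Os12g0108500 by 1.58 (SE 0.10) and the amino acid transporter gene Os04g0201500 by 1.54 (SE 0.13). The opposite held for Os01g0147700 (-3.85, SE 0.32), Os01g0781000 (-3.61, SE 0.11), Os03g0299200 (-2.90, SE 0.40), Os04g0326300 (-2.65, SE 0.16) and Os06g0254300 (-2.25, SE 0.14). Of these 10 genes all but Os12g0108500 were called in sheath. The cellulose synthase genes of the blade differed as well, by -1.31 for Os07g0208500, -1.09 for Os05g0176100 and -1.10 for Os07g0252400.

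In all, 162 genes differed by limma, 48 higher and 114 lower in blade than in sheath, 142 of them by at least 2-fold; 2679 had an unadjusted p under 0.05. Leaving out 1 array gave 48 (without sheath array 3) to 480 (without blade array 1), and trend and robust variance 12. With slide as a block, which rests on the slide that held both tissues, there were 218 (36 higher, 182 lower). With the replicate as a block there were 76, with Os01g0116400 (adjusted p = 0.114) and Os03g0299200 (adjusted p = 0.110) no longer called, and with each WT RNA counted once there were 35. Ribosomal protein genes had a median difference of 0.39 (camera adjusted p = 1.84e-12; adjusted p = 0.899 with an estimated correlation), or 0.16 with slide as a block (adjusted p = 0.00640). Secondary wall and lignin genes had a median difference of -0.42 (camera adjusted p = 0.000263; adjusted p = 0.899 with an estimated correlation), or -0.23 with slide as a block (adjusted p = 3.07e-05).

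The average over both tissues asked what moved with RDD2-OX in the leaf as a whole, over 6 arrays. Os02g0568200, the non-phototropic hypocotyl gene, fell by 1.70 (SE 0.10, adjusted p = 0.00113) and was called in each tissue. The catalase A gene Os02g0115700, for an enzyme that breaks down hydrogen peroxide, rose by 1.59 (SE 0.26, adjusted p = 0.0490), and an alpha-amylase gene, Os08g0473900, by 0.93 (SE 0.13, adjusted p = 0.0331). Os01g0781000 rose by 1.93, Os01g0144100 by 1.31 and the glycosyltransferase gene Os04g0324100 by 0.94. Os10g0491000 fell by 1.52, Os10g0490800 by 1.36, Os07g0645000 by 1.14 and the amino acid carrier gene Os12g0194900 by 0.94. Of these, Os01g0781000 and Os04g0324100 also passed the test of the difference between tissues, so that their average stands mostly for the sheath. For the others, not passing that test does not make the change alike in both tissues. Os07g0645000 was called in blade but not in sheath, and Os01g0144100, Os10g0491000 and Os10g0490800 in sheath but not in blade.

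In all, limma called 387 genes on average, 231 higher and 156 lower, and 82 of them by at least 2-fold, with 5217 at an unadjusted p under 0.05. Leaving out 1 array gave 60 (without sheath array 3) to 924 (without blade array 1; 433 higher, 491 lower), the stricter filter 75 higher and 77 lower, and trend and robust variance 10. With the replicate as a block there were 122, and with each WT RNA counted once 40, which held Os02g0568200 (adjusted p = 0.0221) and Os01g0781000 (adjusted p = 0.00247). The secondary wall list had a median of -0.26 on average (camera adjusted p = 3.46e-08; adjusted p = 0.443 with an estimated correlation).

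The responses of the tissues were compared across genes, which are not independent replicates: Pearson's r was 0.154 and Spearman's rho 0.187 over 25403 genes, with -0.09 to 0.25 between single arrays of different tissues. Between arrays of the same tissue r was 0.01 to 0.36 in blade and 0.28 to 0.83 in sheath. The blade arrays thus agreed little with each other, so the low r does not show that the tissues respond differently. With median centring Pearson's r was 0.408. The called sets shared 3 genes, all lower in both tissues, where 0.125 would be shared if the calls were independent, which a shared spread per gene and a fixed dye orientation do not make them; 0 genes were higher in both and 0 went opposite ways. Apart from Os02g0568200 these were Os07g0640300, with a nucleic acid-binding OB-fold (blade -1.32, sheath -0.69), and Os08g0462900, of a family of unknown function (blade -1.06, sheath -0.71), both named after their values were seen.

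RDD2 belongs to the Dof transcription factors, a plant family with a single zinc finger, some of whose members act on flowering time. The Dof, clock and flowering lists were therefore read gene by gene. Of 19 Dof genes 0 were called in either tissue by limma (camera adjusted p = 0.959 in blade, 0.823 in sheath), and 1 rose in sheath adjusted over the list alone. Of 31 Dof probes, 1 read above 0.5 on all 6 arrays: the coding-sequence probe of Os07g0685000, at 3.68, 0.89 and 1.29 in blade and 3.39, 2.64 and 2.17 in sheath. With limma run on single probes it passed on average over both tissues (2.345, SE 0.377, adjusted p = 0.0461), but not in blade (adjusted p = 0.164) or in sheath (adjusted p = 0.108). The probe that stands for this gene, which covers the coding sequence and the 3' untranslated region, read 3.62, -0.65 and 0.01 in blade and 3.51, -0.36 and 0.06 in sheath. Nothing in the files ties this gene to RDD2, and it was singled out after its values were seen.

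**Figure D3:**
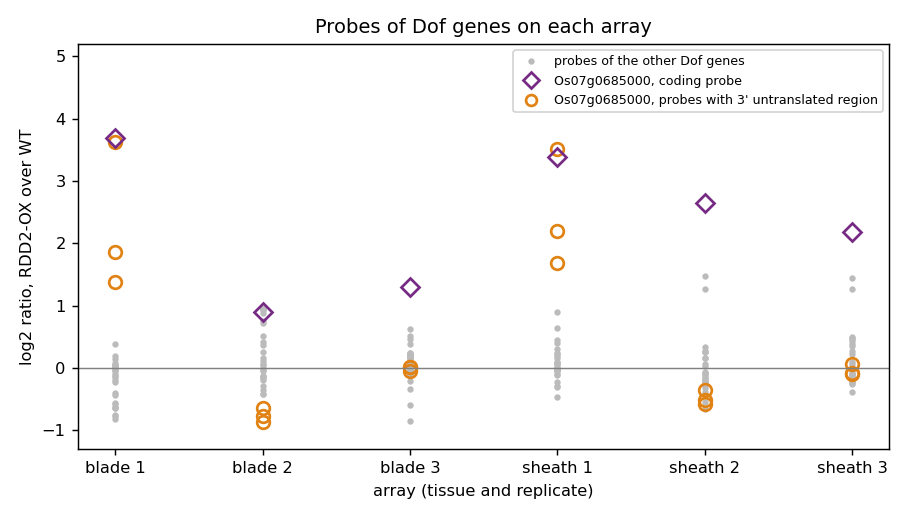
Log2 ratio of RDD2-OX over WT (vertical axis) of the 31 Dof probes on each of the 6 arrays (horizontal axis). Diamonds mark the coding-sequence probe of Os07g0685000, which lies at 0.89 or above on all 6 arrays, orange circles its 3 probes that reach into the 3' untranslated region, which are above 1 only in replicate 1 of both tissues, and the remaining markers the other Dof probes.

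Of 13 clock genes 0 were called in blade or sheath by limma, and 0 adjusted over the list alone; the list's camera adjusted p was 0.982 in blade, where its median of 0.04 is above 0 while the test points lower, and 0.120 in sheath. In sheath GIGANTEA, Os01g0182600, had a log2 ratio of 1.62 (SE 0.55, adjusted p = 0.285) and FKF1, Os11g0547000, of 1.61 (SE 0.88, adjusted p = 0.491). Both belong to the evening part of the clock that times flowering by day length. At the preset correlation the clock list passed in sheath with the replicate as a block (camera adjusted p = 0.0197), with median centring (0.0321), with the mean over all probes (0.0454) and without blade array 2 (0.00788). It did not pass in the test as reported (adjusted p = 0.930 with an estimated correlation). Of 14 tested flowering genes 0 were called (camera adjusted p = 0.944 in blade, 0.401 in sheath), and the MADS-box gene Os03g0752800 had 0.29 in sheath with adjusted p = 0.304. Of 9 iron genes 0 were called in blade (camera adjusted p = 0.613) or in sheath (0.693).

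The comparison of tissues within a genotype gives the background to these responses. In WT, the named genes with the highest blade over sheath values were Os03g0843800 (log2 difference 6.74, SE 0.69), Os08g0299400 for monogalactosyldiacylglycerol synthase, which makes a main lipid of chloroplast membranes (6.56, SE 1.27), Os06g0228500 (6.42, SE 0.57), Os06g0229000 for the chloroplast protease FtsH (6.12, SE 0.39) and Os10g0529700 for a glutathione transferase (SE 0.28, and 5.83 in RDD2-OX). The named genes with the lowest values were Os04g0465600 (-8.98, SE 0.59), Os01g0799500 (-8.03, SE 0.32), Os06g0160100 for histone H3 (-7.86, SE 0.28), Os04g0640700 (-7.82, SE 0.30) and Os06g0696400 (-7.78, SE 0.29). The rule behind these names asks for signal well above background on all arrays and for no overlap of blade and sheath values. RDD2-OX gave the same signs, from 5.77 to 6.79 for the genes higher in blade and from -9.59 to -7.41 for those higher in sheath.

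In all, 6376 of 24836 genes differed between WT tissues by limma, 3178 higher and 3198 lower in blade, from 2 RNAs against 1, whose spread rests on the pair of blade RNAs. The split by direction depends on the setting. It was 2827 higher and 1885 lower with the stricter filter, 11268 and 8189 with all 6 WT channels apart, and 10861 and 7688 with lmscFit, a limma fit of both channels. Between RDD2-OX tissues, from 3 RNAs against 3, 16652 of 24941 differed, 9986 higher and 6666 lower. Of 6360 WT calls tested in RDD2-OX, 6262 were called the same way and 4 the opposite way. Those 4, named after their values were seen, were Os01g0147700, the kinase gene Os01g0113400, and Os03g0651700 and Os08g0338000 of unknown function. Slide 3 held all sheath arrays and 1 blade array, and with slide as a block 17371 genes differed in RDD2-OX.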

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

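The list tests of the difference and the tests of neighbouring loci, of dye bias, of WT RNA in sheath, of lists higher in sheath and of the Dof probes were chosen after the results were seen. For the wall genes the other tests were fixed first, but the rule that reads the percentiles of random lists was made stricter afterwards. This turned the explanation by a single array or WT RNA from excluded to open, and its array and WT RNA parts were later read apart. The reading of the splits on average was made stricter as well, which left it open. The tissue share was read several times after its values were seen: matched lists first excluded it and were then found to decide nothing, and lists higher in sheath excluded it under 1 tissue contrast but not when 3 were used, which is the reading given here.

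By a direct test of the difference, blade minus sheath, the ratio of RDD2-OX to WT differed between tissues for 162 genes (48 to 480 on leaving out 1 array, without sheath 3 and without blade 1). There were 81 without genes seen or missing in WT sheath alone, 35 with each WT RNA counted once and 12 with trend and robust variance. All sheath ratios share 1 WT RNA, so the difference may come from that RNA as well as from RDD2-OX. The test of the difference also passed for the secondary wall and lignin list (median -0.42) and the ribosomal protein list (median 0.39), at a preset correlation only (adjusted p = 0.899 for each with an estimated correlation). Among genes that moved in blade, the difference was -1.31 for Os07g0208500, -1.09 for Os05g0176100 and -1.10 for Os07g0252400, the cellulose synthase genes, and -0.97 for the fasciclin gene Os09g0248100. It was -1.38 for the tubulin gene Os03g0661300, -1.38 for the NAC gene Os07g0683200, -1.55 for Os08g0459300, -1.16 for Os09g0494200, -1.01 for Os03g0815200 and -0.96 for Os12g0623900. For genes that rose in blade it was 1.58 for Os12g0108500, 1.53 for Os07g0509800 and 1.25 for Os03g0319400.

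Among genes that moved in sheath, the difference was -6.61 for Os01g0148400, -6.34 for Os04g0338100, -4.67 for Os02g0615800, -3.85 for Os01g0147700, -3.61 for Os01g0781000, -3.44 for Os10g0137700, -2.90 for Os03g0299200, -2.65 for Os04g0326300, -2.25 for Os06g0254300, -2.02 for Os08g0250700 and -1.41 for Os04g0324100. WT sheath was not well above background for the first 3 or for Os10g0137700, so these values are no measured folds. For genes that fell in sheath it was 3.28 for Os01g0827400, 2.58 for Os04g0116800, 1.99 for Os01g0116400, 1.74 for Os05g0146700, 1.54 for Os04g0201500 and 1.33 for Os10g0543400. Os04g0116800 was not well above background in blade, so its value is no measured difference in response. Adjusted p-values of all these genes ran from 7.25e-05 to 0.0459.

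Other splits of the arrays were counted for each result. Of the 4 ways to set the signs of 3 arrays, the real one gave 39 genes in blade and the highest other 0 by limma (1282 to 3196 at an unadjusted p), and in sheath 284 against 0 (20 to 1419). Of the 10 splits of 6 arrays, the real one gave 162 genes for the difference and the highest other 0 (160 to 2501 at an unadjusted p). It gave 16652 for the tissues of RDD2-OX, with 0 as the highest other (11 to 284). In each of these only 1 split, the real one, gave as many, and the splits are too few for a share under 0.05. Where pairs of same-numbered replicates are kept in view, 3 other splits part all 3 pairs as the real one does, and these gave 0 as well. On average over both tissues 1 of 32 splits, the real one, gave 387 genes, and the highest other gave 187. The arrays share WT RNAs, however, and same-numbered replicates may share a line. Turning the signs of arrays with the same WT RNA together leaves 4 splits (highest other 187), and turning them by same-numbered pair also 4 (highest other 0), too few for a share under 0.05. The 7 others that kept the sheath signs gave 98 to 187, so that sheath carries part of this count.

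One pattern is a set of genes for which WT sheath stood apart from RDD2-OX sheath and from both genotypes in blade. By the flags for signal well above background, 104 genes were missing in WT sheath alone and 17 were seen there alone. Of these, 45 and 9 were called changed in sheath, so for the rest the flags alone set WT sheath apart. Dye bias of the probes is argued against for the 173 sheath calls of at least 2-fold. In blade their probes gave a median ratio, turned to the sheath sign, of 0.072 (upper quartile 0.27), where the median size in sheath was 1.78. That 138 of 284 changed genes had a changed neighbour within 5 loci, against 55 in blade, 45 between RDD2-OX tissues and 51 between WT tissues for as many genes, is consistent with WT sheath RNA from plants of another genotype, which may differ in stretches of the genome. RDD2 overexpression in the sheath stays open too, with 51 calls when each WT RNA counts once, because 1 WT RNA of the sheath cannot show how WT plants vary. The neighbour count between WT tissues cannot decide this. Another genotype would also enter there, but the genes counted have the lowest p among 6376 calls, which differences between tissues can fill. The pattern was found and tested on the same data.

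Another pattern is the Dof gene Os07g0685000, whose coding-sequence probe was high on all 6 arrays while its 3 probes that reach the 3' untranslated region were high in replicate 1 only. A fault of a single one of those 3 probes is argued against, since the lowest r between them over the arrays was 0.980. An overexpressed transcript that carries the 3' untranslated region in replicate 1 only stays open: 1 of 302 genes, this one, had so wide a range of the gap between the kinds of probe (3.13), but the gene was picked for that gap, so the count does not speak for it. It also stays open, and was not tested, that the coding-sequence probe is at fault or reads another transcript.

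The last pattern is the lower secondary wall and lignin genes in the RDD2-OX blade. There 2 of 68 genes passed, both for fasciclin domain proteins, and the list passed at the preset correlation only (adjusted p = 0.476 with an estimated correlation). Normalization is argued against as the cause of that call, since at the preset correlation the highest adjusted p over 7 background, scaling and filter settings was 1.35e-07. A single array is argued against: the array medians were -0.06, -0.56 and -0.26, and those of arrays 2 and 3 were both at percentile 0 among random lists. The WT RNA that arrays 2 and 3 share may still carry it. In array 1 the percentile was 2.33, too near the limit of 2.5 for its sampling error, and random lists leave out the correlation between genes. A lower share of sheath-like tissue stays open: in replicates 2 and 3 the ribosomal protein, expansin, cuticle and shoot meristem lists, more sheath-biased than the wall list under 3 tissue contrasts, had medians of 0.038 or more, but under the WT tissue comparison so were the xyloglucan and cellulose list (-0.13) and the housekeeping list (-0.08), whose bootstrap intervals overlap that of the wall list (-0.46, interval -0.62 to -0.16). Another share of growing tissue stays open beside an effect of RDD2, since random lists matched on the WT tissue difference (percentile 1.78 or lower) hardly moved.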

How the results depend on the processing

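The tests with each WT RNA counted once, that of the WT tissues included, and without genes seen or missing in WT sheath alone were chosen after the data were seen. In genotype comparisons, counting each WT RNA once also dropped the pairing of channels on an array. The sign was followed for 23 named genes in blade, 31 in sheath, 10 in the difference and 10 on average. Genes named for the tissue comparisons were left out. No gene followed, and no correlation, turned its sign under the alternatives run. With median centring the ribosomal protein list in sheath did (median 0.06, adjusted p = 0.797), as did the medians of HD-ZIP III genes in blade (0.02) and of secondary wall genes in sheath (0.05). More genes were higher than lower in blade with median centring (4830 and 3804, against 6 and 33), and more lower than higher on average without blade 1 (433 and 491) and with the stricter filter (75 and 77, against 231 and 156). Between WT tissues more were higher than lower in blade with the stricter filter (2827 and 1885, against 3178 and 3198), among other settings. Of the alternatives for named genes, 219 in blade kept direction and side of the threshold, 191 lost the call and 4 gained it; in sheath these were 451, 98 and 1, in the difference 147, 33 and 0, and on average 120, 60 and 0. Unless the construction is given, the cause was not tested.

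The blade count of 39 was 144 from Agilent's processed signals, 136 from the series matrix, 8634 with median centring, 1 with scaling between arrays and 3 with slide as a random block. Limma gave 0 with trend and robust variance (3819 at an unadjusted p), the replicate block (4375), the 3 blade arrays alone (2181) and each WT RNA once (747). All 39 genes remained with the processed signals, the matrix and median centring. The share higher moved from 15.4% to 47.2%, 46.3% and 55.9% in these. Median centring moved the median gene by 0.19 in blade and 0.10 in sheath.

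The sheath count of 284 was 440 with median centring (240 of 284 remained; 51.1% higher against 66.2%), 444 with scaling, 46 with trend and robust, 189 with the replicate block (166 remained), 106 with slide as a random block, 51 with each WT RNA once, and 112 when both channels had to be well above background, which left 143 of the 284 in the test. The average of 387 was 9327 with median centring (333 remained and 13 of the 387 turned sign), 10 with trend and robust, 122 with the replicate block, 48 with slide as a random block, 40 with each WT RNA once, 152 with the stricter filter, and 226 without the genes seen or missing in WT sheath alone. The difference of 162 was 312 with median centring, 12 with trend and robust, 76 with the replicate block, 35 with each WT RNA once, 45 with the stricter filter and 81 without those genes.

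WT tissues differed in 6376 genes, and in 19457 with all 6 WT channels apart, as first fixed, or 18549 with lmscFit, which count 1 RNA several times; RDD2-OX tissues in 13470 to 18332 under every alternative run. The correlation of 0.154 rose to 0.408 with median centring. Against 4 lists in blade, 0 passed with camera's estimated correlation (3 at an unadjusted p), 9 with each WT RNA once and 9 with median centring. Against 4 in sheath, 2 passed with the processed signals, 0 with an estimated correlation (0 at an unadjusted p), 8 with median centring and 1 with slide as a random block. With the replicate block 6 passed in blade and 5 in sheath.

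Leaving out 1 array at a time gave 0 to 760 in blade: 760 without blade 1, 4 without sheath 2, and 0 without blade 3, sheath 1 or sheath 3 (3801, 3271 and 2685 at an unadjusted p). Sheath gave 93 (without sheath 3) to 324, with 116 without sheath 1. The average gave 60 (without sheath 3) to 924 (without blade 1), with 191 without blade 3, 89 without sheath 1 and 181 without sheath 2. The difference gave 48 (without sheath 3) to 480 (without blade 1), with 82 without blade 3, 61 without sheath 1 and 95 without sheath 2. Without blade 1 each tissue has 1 WT RNA, so the counts of 760, 924 and 480 leave out the spread between WT plants. The WT tissues gave 6368 to 6933, RDD2-OX tissues 13850 to 17065, and the correlation 0.102 to 0.191. Lists in blade gave 4 to 10 (10 without blade 2), and in sheath 1 (without sheath 1) to 6, with 2 without blade 3.

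WT tissues without blade 1, and with replicate or slide as a block, had no spread left to test and gave no value. Signal limits what can be seen in WT blade most, where the median above background was lowest, at 243 to 291.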

Other observations

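The list tests between tissues in this part were added after the data were seen. Between RDD2-OX blade and sheath, the lists with the lowest camera p were lower in blade. Of the ribosomal protein genes 10 were higher and 224 lower (median -1.38, and -1.76 in WT; camera adjusted p = 5.68e-16; adjusted p = 0.505 with an estimated correlation). Cuticle and lipid transfer genes had a median of -1.91 (5 higher, 38 lower, adjusted p = 1.07e-08; 0.142 with an estimated correlation) and expansins, which loosen growing walls, of -1.88 (2 higher, 21 lower, adjusted p = 6.22e-07; 0.120 with an estimated correlation). Secondary wall and lignin genes had -1.26 (adjusted p = 5.27e-06; 0.396 with an estimated correlation). By median, the 6 diterpenoid phytoalexin genes stood furthest apart, at 2.13 (adjusted p = 0.137; 0.641 with an estimated correlation). Phosphate genes were higher in blade (median 1.07; 25 higher, 6 lower; adjusted p = 0.0112; 0.461 with an estimated correlation).

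Single arrays held further values, for genes named after these were seen. FKF1, Os11g0547000, read 4.10 in blade and 2.97 in sheath in replicate 2, 0.02 and 1.88 in replicate 3, and 0.50 and -0.02 in replicate 1. GIGANTEA, Os01g0182600, read 1.31 and 2.74 in replicate 2, -0.42 and 1.75 in replicate 3, and -0.91 and 0.36 in replicate 1. The response regulator gene Os09g0532400 read 2.58 and 2.26 in replicate 2, -0.03 and 1.67 in replicate 3, and -0.02 and 0.43 in replicate 1. In blade replicate 3 the FKF1 log2 signals were 6.23 in WT and 6.25 in RDD2-OX, so low that the 0.02 does not show a lack of change. The sheath arrays share 1 WT RNA, and the RDD2-OX log2 signal of FKF1 there was 6.96, 9.98 and 8.79 in replicates 1, 2 and 3. The labels give 2 h for all samples, and whether each was taken at that time is not known here. The nicotianamine synthase genes Os03g0307300 and Os03g0307200, of iron uptake, read -7.94 and -6.73 in blade array 1 alone, where the WT log2 signal of the first was 15.81 against 6.78 and 6.54 in the other blade arrays. A further nicotianamine synthase gene, Os07g0689600, read 1.32 in blade array 1, and -0.79 and -0.51 in the other blade arrays.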
